A study of Mus musculus with 25 samples.

How the data were processed

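Gametogenesis in mice that lack or carry altered YTHDC2, an RNA helicase with a YTH domain that germ cells need to pass from mitosis into meiosis, was profiled by single-cell RNA-seq, bulk RNA-seq and iCLIP, a crosslinking method that maps where a protein touches RNA. The single-cell part holds 1 wild-type (WT) and 2 knockout (KO) samples of postnatal day 10 testis cells sorted for a 4N DNA content, which both cycling cells after replication and cells in meiotic prophase have. The titles of these samples carry the word embryo beside P10; the age label, postnatal day 10, was followed, and testis comes from the extraction protocol. Per the labels, the mutant lines were kept on a hybrid background of 2 inbred strains, C57BL/6 and DBA/2. Bulk RNA-seq of sorted 2N and 4N cells from postnatal day 60 (3 +/YTHmut and 3 YTHmut/YTHmut samples of each sort), bulk RNA-seq of day 14 testes (4 wt and 4 E332Q samples) and 2 iCLIP samples of day 15 testes belong to the same series and were not analysed here.

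Reads of the single-cell libraries were processed with Cell Ranger 3.0.2 and Scanpy against mm10/GRCm38, per the submitters' processing notes. The deposited matrix of 4528 cells and 14103 genes holds natural log values, ln(1 + count/size factor), made by the authors. The deposited cell table gives each cell's library, its cluster, its size factor (a score), its UMI count and number of genes (counts before the authors' scaling), its mitochondrial fraction, and a log2 sum over genes with a U-rich motif. A further log2 sum in the cell table is named ubiq. The deposited gene table gives a U-motif score per gene. Every cell held at least 3000 genes and less than 20% mitochondrial UMIs. Undoing the log and the size factor gave whole numbers for 100% of the values above 0, within 0.001, and the number of genes detected matched the deposited number in 4528 of 4528 cells. The recovered counts held 99.9% of the deposited UMI totals. The planned cell filter (1000 UMIs, 500 genes, 20% mitochondrial) removed 0 cells.

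Cells were assigned to libraries by the deposited sample number. The 2 KO libraries, here KO A and KO B, could not be tied to a particular one of the 2 KO samples. The authors' clusters were used and are numbered here: cluster 1 is their undifferentiated spermatogonia, cluster 2 their differentiating spermatogonia, cluster 3 their leptotene-zygotene spermatocytes, and clusters 4 and 5 are 2 clusters that their names describe as a mix of differentiating spermatogonia and leptotene-zygotene cells. Among the 10 leading genes by fold of cluster 1, 0 were markers of its own type and 2 were markers of peritubular myoid cells. Tcf21 and Col1a2, also among these 10, were stromal markers. Of the 10 leading genes of cluster 2, 0 were its own and 2 were red blood cell markers. Results are therefore given by cluster number. Cells with at least 10 UMIs of smooth muscle, stromal or globin genes numbered 34, of which 33 were in cluster 1. Doublets were called per library with Scrublet in Scanpy (8 of 1151 WT cells, 7 of 1522 KO A cells, 36 of 1855 KO B cells) and kept in the main result.

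The following classes were compared between KO and WT: all germ cells, clusters 1 and 2 together, and clusters 3, 4 and 5 together. For each class and library the mean of count/size factor over cells (normalised UMIs per cell) was computed. Genes with a mean of at least 0.05 were tested on log2(value + 0.01) with limma 3.58.1 (R 4.3.3), with empirical Bayes moderation, a mean-variance trend and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Folds printed are ratios of the mean values, and log2 changes are on the log2(value + 0.01) scale, which understates the change of low genes. Before the data were examined, edgeR on raw UMI counts had been set as the main test, with limma on mean values if only normalised values were deposited. The second applied, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered counts as alternatives. The spread came from the 2 KO libraries alone, with 1 residual degree of freedom per gene, so the lone WT library is assumed to vary as they do. The smallest exact p that 1 library against 2 can give is 0.333, so adjusted p values rest on the spread that limma shares across genes (prior degrees of freedom 25.0 for all germ cells, 10.8 for clusters 1 and 2, and infinite for clusters 3, 4 and 5). Whether the KO libraries came from different animals is not given in the sources used here, and p values then measure only the spread between these libraries, which may be technical. Genotype and library cannot be told apart in WT, and no batch label was given.

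Of the named genes, Ythdc2, Meioc, Rbm46 and Xrn1 were fixed in advance. In each class the rule then took the 10 genes with the smallest p in each direction among called genes with an absolute log2 change of at least 1, a mean of at least 10 counts per 1e6 UMIs (CPM) and both KO libraries on the same side of WT, leaving out predicted gene models and ribosomal protein genes. The rule also took up to 4 members of each gene list with the smallest p. Genes that met these criteria numbered 190 in all germ cells, 47 in clusters 1 and 2 and 1243 in clusters 3, 4 and 5. The lists were fixed in advance: mitotic M-phase, S phase, undifferentiated and differentiating spermatogonia, meiotic entry, synaptonemal complex and cohesin, meiotic recombination, pachytene, piRNA pathway, p53 response and apoptosis, integrated stress response, dissociation and immediate early genes, m6A machinery, RNA decay, retinoic acid response, mitochondrially encoded genes, the YTHDC2 complex and Sertoli cells. Lists were tested against the other genes with camera in limma at a preset correlation of 0.01, adjusted over the lists of a class, and again with an estimated correlation. At the estimated correlation no list held its call in any class. That version rests on 1 residual degree of freedom, so it could hardly pass any list and these losses decide nothing. The preset correlation is itself an assumption. Positions are from the RefSeq annotation of GRCm38.p6, the build of the submitters' notes. Of 14103 genes, 13319 were matched to it by Ensembl identifier or symbol.

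For shares of cells with a UMI and for UMIs per cell of a list, each cell was thinned to 5000 UMIs with a fixed seed, which left out 0 cells. Intervals are 95% exact Poisson or binomial intervals and cover counting error only. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.

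The fits were tested on simulated data made from the real means and library sizes, with 100 genes changed by log2 1 and 100 by log2 0.5. In all germ cells limma found 94% and 38% of them among 9628 genes, against 97% and 32% with edgeR and 78% and 7% with DESeq2. In clusters 1 and 2 limma found 93% and 31% among 9789 genes, and in clusters 3, 4 and 5 98% and 59% among 9325 genes, where 29 unchanged genes were also called. It called 11 unchanged genes in all germ cells and 9 in clusters 1 and 2. All simulated libraries, WT included, shared one spread and had no batch. The check therefore cannot show how the fits fare if the lone WT library differs in these.

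Alternatives set in advance were doublet removal, no filter on low values, edgeR with RLE size factors, DESeq2, clusters of these cells made anew (Leiden resolution 2), leaving out each KO library, and, for the lists, RLE scaling and the estimated correlation. edgeR with TMM, the main test set for raw counts, and Leiden resolution 1 had also been named in advance, and were run as alternatives. Limma and the authors' clusters took their place in the main result. Others were added after seeing the data: TMM scaling in limma, robust moderation, pseudocounts of 0.001 and 0.1, and cells with 10000 UMIs or more. So were equal cell numbers, removal of the 34 cells, single clusters and DESeq2 without its filter on low means. The cuts of 20 and 30 M-phase UMIs for co-detection were also chosen then. Together 50 fits were made. Genes with near-identical copies (tubulins, ribosomal protein genes, H2 genes, predicted pseudogenes) are uncertain where counting could split their reads.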

Results

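Testis cells of postnatal day 10 with a 4N DNA content were profiled from 1 WT library of 1151 cells and 2 Ythdc2 KO libraries, KO A with 1522 and KO B with 1855 cells. Total depth was 16342955 UMIs for WT, 18089957 for KO A and 25447581 for KO B, and the median cell held 12827, 9760 and 12091 UMIs. The KO libraries were not one library deposited again, since their counts differed by 14.5 in chi-square per degree of freedom over 13366 genes. Clusters 1 and 2 held 45 and 654 WT cells, 66 and 529 KO A cells, and 90 and 814 KO B cells. Cluster 3, the authors' leptotene-zygotene cluster, held 427 WT cells and 0 of 1522 KO A and 0 of 1855 KO B cells, which allows a share of up to 0.242% and 0.199% (exact upper limits). Clusters 4 and 5 held 592 and 335 KO A cells and 441 and 510 KO B cells, against 24 and 1 WT cells. The 3 together made up 39.3% of WT cells (exact interval 36.4 to 42.2), 60.9% of KO A cells (58.4 to 63.4) and 51.3% of KO B cells (49.0 to 53.6). With cells clustered anew at resolution 2 the order turned, with 61.1% of WT, 57.4% of KO A and 43.0% of KO B cells. At resolution 1 the authors' order was kept, with 462 of 1151 WT, 931 of 1522 KO A and 958 of 1855 KO B cells. These shares describe the sorted suspensions, since the 4N sort sets which cells are seen and the genes that define the clusters differ between genotypes.

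Ythdc2 itself (ENSMUSG00000034653, chromosome 18, 44827730 to 44889720) stood at 196 CPM in WT (exact Poisson interval 189 to 203), 47.0 CPM in KO A (43.9 to 50.3) and 42.6 CPM in KO B (40.1 to 45.2), in the direction of the labels. After thinning, a Ythdc2 UMI was seen in 60.6% of WT, 22.6% of KO A and 21% of KO B cells, against 87.7%, 41.2% and 43.2% before it. No cluster of a cell type that should lack Ythdc2 was captured, so the background share is open. By cluster its level in WT was 37.7 CPM in cluster 1, 170.0 in cluster 2 and 266 in cluster 3. In the KO libraries it was 25.7 and 22.8 CPM in cluster 1, 50.4 and 44.2 in cluster 2, 61.5 and 64.0 in cluster 4, and 35.3 and 34.9 in cluster 5. Which part of the gene is missing in the KO allele is not given in the sources used here, so UMIs from outside it can remain. Of the partners fixed in advance, Meioc, which binds YTHDC2, was 1.40-fold lower in all germ cells (log2 -0.49, SE 0.14; limma, adjusted p = 0.0101) and 1.59-fold lower in clusters 3, 4 and 5, and its log2 difference of -0.48 in clusters 1 and 2 did not pass (adjusted p = 0.0612). Rbm46, an RNA-binding partner, had log2 differences of -0.07, -0.01 and -0.11 in all germ cells, clusters 1 and 2, and clusters 3, 4 and 5, none past the test. Xrn1, the 5' to 3' exoribonuclease, was higher in clusters 3, 4 and 5 (log2 0.46, SE 0.12; limma, adjusted p = 2.1e-04) and not past the test elsewhere, and DESeq2 and clusters made anew at resolution 2 did not call it. For the YTHDC2 complex as a list, camera gave adjusted p = 0.102, 0.0496 and 0.0244 in these classes, and 0.666, 0.488 and 0.540 with an estimated correlation. With RLE scaling it was 5.7e-04, 0.0678 and 0.145.

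To set the genotypes beside the replicate spread, pairs of libraries were compared over genes at 20 CPM or more. Of 6808 genes, 125 differed by a log2 of 1 or more between KO A and WT (104 higher and 21 lower in KO A) and 104 between KO B and WT (73 higher, 31 lower), against 3 between the KO libraries. With equal numbers of cells per library the counts were 135, 131 and 4.

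In all germ cells together, Cox7b and Reep5 led the transcripts that were higher in KO by p value, Ythdc2 and Eaf2 led those that were lower, and most genes of the meiotic recombination and synaptonemal complex lists fell. Cox7b, a subunit of cytochrome c oxidase, rose 5.34-fold, from 0.429 normalised UMIs per cell in the WT library to 2.29 ± 0.0545 (SD, n = 2) in the KO libraries, and Cox8a, another subunit, rose 3.83-fold. Reep5, a shaper of the endoplasmic reticulum, rose 4.98-fold, the transcription factor Klf2 3.74-fold and the chromatin remodeller Chd9 4.24-fold. Among meiotic genes, the cohesin subunit Rad21l fell 4.77-fold, from 0.763 normalised UMIs per cell in the WT library to 0.160 ± 0.0230 (SD, n = 2) in the KO libraries, Rad51ap2 4.78-fold, the telomere attachment gene Terb1 3.28-fold, the meiotic cyclin Ccnb3 4.16-fold and the transcription factor Figla 4.90-fold. Eaf2, a transcription elongation cofactor, fell 5.15-fold. Other genes that the rule named included Tkt, Prdx3, Mbd2 and Lonp1, which rose by a log2 of 1.54 to 2.08, and Tmsb4x, Dnpep and H2-Ab1, with log2 changes of -1.63, -1.45 and -2.20. DESeq2 did not call Tmsb4x. Tmsb4x UMIs lay mostly in cluster 1, at 857 CPM in the WT library and 379.7 and 218 CPM in KO A and KO B, and was at 2.74 to 3.40 CPM in cluster 2.

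Of the meiotic lists, 15 of 19 measured recombination genes fell and 0 rose (median log2 -0.75), and 10 of 14 synaptonemal complex and cohesin genes fell and 0 rose (median -0.70; 12 adjusted over the list alone). Meiob, which works in strand exchange, had a log2 change of -2.21, and Syce3 and Tex12 of the synaptonemal complex -1.43 and -1.37. Of 7 meiotic entry genes 5 fell, with Meiosin (listed as Gm4969) at -1.40 and Zcwpw1 at -0.76, while Stra8 and Rec8 did not pass (0.29 and 0.19). Of 9 differentiating spermatogonia genes 5 rose, among them Sohlh1 (0.92), Ccnd2 (0.90) and Kit (0.76), and of 10 retinoic acid response genes 4 rose, among them the receptors Rxra (0.82) and Rarg (0.71, not called by DESeq2). Adjusted over the list alone the counts of all lists were the same, except for the 12 above, 4 higher immediate early genes and 1 higher gene (Xrn1) of the YTHDC2 complex. By camera these 5 lists had adjusted p of 1.2e-10, 1.0e-08, 0.00900, 0.00893 and 0.0115, and each had adjusted p = 0.666 with an estimated correlation. The other lists did not pass camera. Mitotic M-phase genes split into 3 higher (Cdk1, Ccnb2 and Birc5), 1 lower (Bub1) and 16 not past the test, but edgeR, with RLE or TMM, and DESeq2 called only 1 of the 20, Bub1, and limma with TMM scaling kept Birc5 of the 3 higher. S phase genes split into 1 higher, 3 lower and 16. Undifferentiated spermatogonia genes counted 2 higher of 3 (0 called by DESeq2), piRNA genes 2 higher and 3 lower of 14, integrated stress genes 5 and 1 of 12 with Trib3 at 1.25, immediate early genes 2 and 1 of 9, and p53 genes 1 (Bbc3, not called by DESeq2) and 1 (Pmaip1) of 11. The m6A list counted 2 higher and 3 lower of 17, RNA decay 0 and 1 (the decapping enzyme Dcp2, -0.71) of 17, pachytene genes 0 and 1 of 3, and mitochondrially encoded genes 3 and 0 of 13, beside a median mitochondrial share per cell of 5.59% in WT, 9.11% in KO A and 6.64% in KO B. Over all 9637 genes tested, limma called 1759 higher and 1429 lower in KO. DESeq2 on the recovered counts called 498 and 698, so the larger side differs between these tests. The mix of clusters enters these values.

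Clusters 1 and 2 were then compared without the others. Cox7b was again higher, 3.37-fold, from 0.632 normalised UMIs per cell in the WT library to 2.13 ± 0.0757 (SD, n = 2) in the KO libraries, as were Cox8a (2.91-fold), the calmodulin kinase inhibitor Camk2n1 (2.27-fold), the mitochondrial protease Lonp1 (2.08-fold), the mitochondrial peroxidase Prdx3 (2.52-fold) and the methionine salvage enzyme Mtap (2.10-fold). The D-type cyclin Ccnd2 rose 2.74-fold. The meiotic cohesin subunit Stag3 fell 2.14-fold, from 2.90 normalised UMIs per cell in the WT library to 1.35 ± 0.0890 (SD, n = 2) in the KO libraries, the synaptonemal complex gene Tex12 2.31-fold, Ccnb3 3.31-fold and the MHC class I gene H2-D1 3.46-fold. Fem1b, Rflnb and Tmem184c rose by a log2 of 1.04 to 1.08, and Tmsb4x, Wdfy1, Nptx2, Ube2cbp and Dmrtc2 had log2 changes of -1.53 to -1.01, with limma adjusted p of at most 0.0410. Calls ended for Ccnd2 and Dmrtc2 with clusters made anew at resolution 2, for Tmsb4x and Dmrtc2 with TMM scaling in limma, for Nptx2 with DESeq2 and for H2-D1 in cluster 2 alone. DESeq2, whose own filter on low means left 10661 of 14100 genes here without an adjusted p, gave none to Camk2n1, Ccnd2, Mtap, Prdx3, Ccnb3, H2-D1, Wdfy1 and Ube2cbp, which it called without that filter, nor to Fem1b, Rflnb, Tmem184c, Tmsb4x and Dmrtc2, which it did not call without it either.

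The 2 clusters did not carry these values alike. Cluster 1 made up 6.44% of their cells in WT, 11.1% in KO A and 9.96% in KO B, and this mix enters the values of genes that lie in cluster 1, such as Ccnd2, Ret and Tmsb4x. Cox7b in cluster 1 was at 128 CPM in the WT library and 126 and 154 CPM in KO A and KO B, and in cluster 2 at 52.2 in WT and 209.9 and 213 in the KO libraries. Ccnd2 lay in cluster 1, at 135 CPM in the WT library and 259 and 247 CPM in KO A and KO B, and reached at most 1.34 in cluster 2. Tmsb4x was at 857 CPM in the WT library and 379.7 and 218 CPM in KO A and KO B in cluster 1, where the cells with smooth muscle, stromal or globin UMIs made up 22.2% of cluster 1 in WT, 15.2% in KO A and 14.4% in KO B. Ccnb3 in cluster 1 was at 5.23 CPM in the WT library and 11.7 and 11.2 CPM in KO A and KO B. Wdfy1 was at 31.4 CPM in the WT library and 12.5 and 11.7 CPM in KO A and KO B in cluster 1 and 25.3, 7.41 and 7.22 in cluster 2. H2-D1 was at 168 CPM in the WT library and 44.0 and 34 CPM in KO A and KO B in cluster 1 and 14, 4.67 and 8.82 in cluster 2.

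Of 6 measured genes of undifferentiated spermatogonia, 3 rose (5 adjusted over the list alone), with the GDNF receptor Ret at a log2 of 1.54, Sall4 at 0.69 and Zbtb16 at 0.67. Ret lay in cluster 1, whose larger share in KO enters the values of this list, at 54.4 CPM in the WT library and 117 and 97.4 CPM in KO A and KO B. Of 9 differentiating genes 2 rose, Kit (0.49) and Ccnd2, whose UMIs lay in cluster 1. Of 14 synaptonemal complex and cohesin genes 6 fell (10 adjusted over the list alone), with Hormad1 at -0.84 and Rad21l at -1.03. Of 16 recombination genes 3 fell (8 adjusted over the list alone), among them Mei4 (-0.87) and Dmc1 (-0.52). Of 7 meiotic entry genes Meiosin (-1.61) and Zcwpw1 (-0.60) fell, and Stra8, which retinoic acid induces, was at 0.60 and did not pass. DESeq2 called 0 of the 6 undifferentiated genes and gave an adjusted p to none of them (1, Ret, without its filter), where edgeR with RLE called 5. Of the differentiating, retinoic acid, mitochondrially encoded and p53 lists it also called 0 here, with 3, 6, 1 and 8 genes left without an adjusted p (1, 0, 0 and 1 calls without the filter). With clusters made anew at resolution 2 the calls of Ret, Sall4, Zbtb16, Kit, Hormad1, Dmc1, Zcwpw1, Rrm2, Ccne2, Rxra and Phgdh ended. The 20 M-phase genes were all below 0 in log2 (median -0.20) and limma called 0 of them (4 at an unadjusted p under 0.05; edgeR called 4 and DESeq2 1), while camera gave adjusted p = 4.8e-04. Their sum in cluster 2 was 9968 CPM in WT and 9172 and 9847 in KO A and KO B, so it was near WT in KO B, and in cluster 1, whose share is larger in KO, it was 7229, 6589 and 6165. For the undifferentiated, differentiating, synaptonemal complex, recombination and meiotic entry lists camera gave 2.1e-04, 0.0393, 5.1e-09, 9.5e-06 and 0.0120, for retinoic acid response 0.0162 (2 of 10 higher, Rxra and Kit), for immediate early genes 0.0162 (0 of 13 past the test; 3 higher adjusted over the list alone), for S phase 0.0496 (2 of 20 lower, Rrm2 and Ccne2) and for mitochondrially encoded genes 0.0381 (2 of 13 higher, mt-Nd6 and mt-Atp8). With an estimated correlation each of these had adjusted p = 0.488, except S phase and mitochondrially encoded genes at 0.672. With RLE scaling the differentiating list had 0.0580. Adjusted over the list alone the other counts that moved were 3 higher for differentiating genes, 1 higher and 4 lower for meiotic entry, 3 higher for retinoic acid response, 4 higher for mitochondrially encoded genes, 3 higher and 1 lower for p53 response, 3 and 1 for integrated stress, and 1 and 2 for the YTHDC2 complex. The remaining lists did not pass camera: piRNA (2 of 14 lower, Mael and Ddx4), p53 response (1 of 12 lower, Pmaip1 at -2.04), integrated stress (1 of 11 higher, Phgdh), m6A machinery and RNA decay (0 of 17 each) and pachytene (0 of 3). For the 4 other lists with 0 calls by limma here, immediate early, m6A, RNA decay and pachytene, the counts at an unadjusted p under 0.05 were 5, 5, 4 and 1, and edgeR with RLE called 2, 3, 3 and 1 and DESeq2, with or without its filter, 0 of each.

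limma called 328 genes higher and 162 lower of 9812 in clusters 1 and 2, with 66.9% of calls higher, and the split differed between analyses that each change more than the scaling. TMM-scaled sums in limma called 237 and 303, and edgeR with TMM, the main test set in advance for raw counts, 558 and 701. edgeR with RLE called 809 and 1206, and DESeq2 17 and 161 (20 and 53 without its filter on low means). Cluster 1 alone gave 72 higher and 246 lower, and kept 35 of the 490 calls, against 348 for cluster 2 alone. Of 39 named genes called in clusters 1 and 2, 14 had the opposite sign in cluster 1 alone, none of them with a call there by limma.

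Clusters 3, 4 and 5 compare the cells furthest along in each genotype: 427 of the 452 WT cells were in cluster 3, and all KO cells of this class in clusters 4 and 5. Mitotic regulators were higher in KO there. Plk1, a kinase of mitotic entry, rose 5.38-fold, from 0.529 normalised UMIs per cell in the WT library to 2.85 ± 0.0117 (SD, n = 2) in the KO libraries, the kinase Cdk1 4.98-fold and the spindle checkpoint gene Bub3 5.72-fold. Cox7b rose 21-fold and Cox8a 9.91-fold, and Reep5, the citric acid cycle enzyme Mdh2 and the phosphatase Ptp4a3 rose 7.54-, 6.48- and 5.65-fold. The tubulin genes Tuba1b and Tubb5, which have near-identical copies, rose 17.2- and 7.86-fold. On the other side, Eaf2 fell 9.50-fold, from 2.64 normalised UMIs per cell in the WT library to 0.278 ± 0.0126 (SD, n = 2) in the KO libraries, Figla 9.22-fold, Rad21l 7.36-fold, Rad51ap2 7.18-fold and Syce3 4.42-fold, and Dnpep, H2-D1, Mlf1 and Cbwd1 fell 4.29- to 4.95-fold. SE of the log2 changes of these 19 genes and Ythdc2 lay between 0.10 and 0.15, and the largest limma adjusted p was 3.0e-87. The WT cells in cluster 4, 24 in number and 4 of them called doublets, had Plk1 at 331 CPM, against 328 and 330.4 in the KO cells of that cluster and 41.0 in WT cluster 3, and Cdk1 at 178 CPM against 293, 302 and 48.4. The M-phase list as a whole was not higher in KO within cluster 4, with 9212 CPM in WT against 7863 and 8218 in KO, and 43.5 against 34 and 39 UMIs in the median cell thinned to 5000 UMIs. Eaf2 is at 36792884 to 36875068 on chromosome 16, Plk1 at 122159435 to 122169884 on chromosome 7, Rad21l at 151644366 to 151670622 on chromosome 2, Cox7b at 106015700 to 106022450 on chromosome X and Cox8a at 7215158 to 7217616 on chromosome 19. Reep5 is on the chromosome of Ythdc2 and within 20 Mb of it, at 34344885 to 34374991. The list genes Dcp2 (44380500 to 44424969), Egr1 and Kif20a are also within 20 Mb of Ythdc2, and Dcp2 is the nearest of these.

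**Figure D1:**
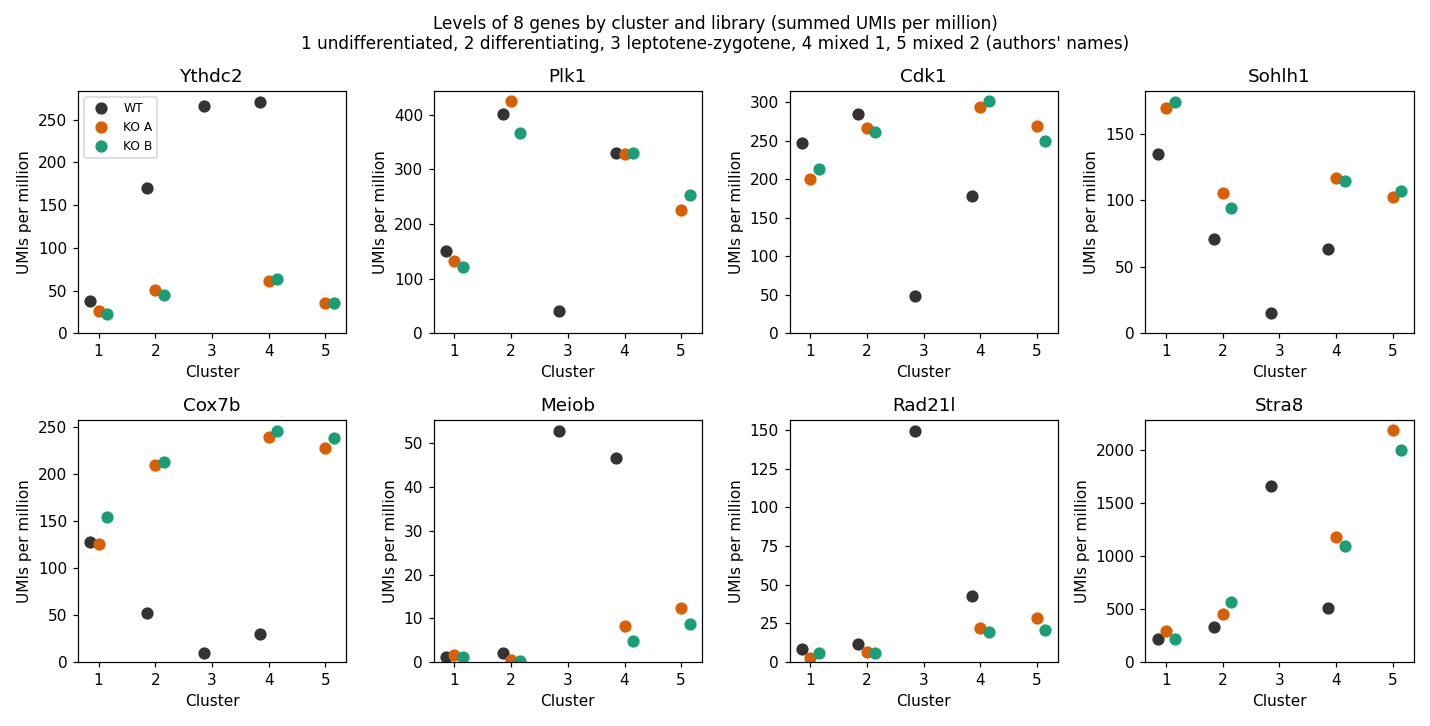
Level in CPM (vertical axis, linear, from 0) of named genes by cluster (horizontal axis), with 1 point per library and cluster, each the summed UMIs of its cells without error bars; cluster 3 has no KO cells and cluster 5 no WT point, as it holds 1 WT cell. In WT cluster 3 Ythdc2 was at 266 CPM and Cox7b at 9.57, and KO points of Cox7b lay between 126 and 246.

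Of the 20 M-phase genes 16 rose, 1 fell (Bub1, -0.78) and 3 did not pass (Top2a, Cenpf and Tpx2), with a median log2 of 1.19, and Aurkb and Ccnb2 at 2.21 and 2.07. Of 8 differentiating spermatogonia genes 7 rose, with the transcription factors Sohlh1 (2.53) and Dmrtb1 (2.38) and the receptor Kit (1.74), and Rhox13 did not pass. Of 20 recombination genes 17 fell, with Spo11, which cuts DNA to start recombination, at -3.25, Meiob at -2.78 and Mcmdc2 at -1.97, and Rec114, Msh4 and Tex11 did not pass. Of 14 synaptonemal complex and cohesin genes 13 fell, with Tex12 at -1.79 and Sycp2 at -1.31, and the cohesin subunit Rec8 rose (0.59). Within cluster 4 the gap was smaller: the median thinned cell held 27 UMIs of this list in 24 WT cells and 23 and 25 in KO A and KO B, against 50 in WT cluster 3. Rad21l was at 42.4 CPM in WT cluster 4 and 21.7 and 19.3 in KO, but Syce3 at 55.1 against 44.2 and 54.6. Of 7 meiotic entry genes 5 fell, with Meiosin at -1.73 and the histone methyltransferase Prdm9 at -1.36, Rec8 rose and Stra8 did not pass (-0.18). Retinoic acid response genes counted 8 higher and 0 lower of 11, with Rxra at 1.69. Immediate early genes, which cell dissociation can raise, counted 6 higher and 1 lower (Egr1, -1.77) of 7, with Dusp1 at 2.70. By camera these 7 lists had adjusted p of 7.4e-14, 3.7e-07, 7.1e-13, 9.1e-10, 0.00414, 0.0284 and 0.0441, and each had adjusted p = 0.540 with an estimated correlation. With RLE scaling the immediate early list had 0.0649. Integrated stress response genes counted 7 higher, among them Phgdh (2.24) and Xbp1 (1.85), and 3 lower of 11, but camera gave adjusted p = 0.116. S phase genes went both ways, 8 higher and 7 lower of 20, with the licensing factor Cdt1 at 1.75 and Dtl, which marks Cdt1 for destruction, at -0.81. The piRNA list counted 2 higher and 6 lower of 13, p53 response 3 and 4 of 10, m6A machinery 7 and 6 of 17, RNA decay 6 and 3 of 17 with Dcp2 among the lower, mitochondrially encoded genes 4 and 1 of 13, and pachytene genes 0 and 1 (Hspa2, -1.50) of 3, and none of these passed camera. The mitochondrial share of the median cell differed by cluster, at 5.50% in WT cluster 3, 10.4% and 9.02% in KO cluster 4 (12.3% in its WT cells), and 4.73% and 4.28% in KO cluster 5. Adjusted over the list alone the counts in these clusters were the same, except for 4 higher p53 genes. Median, mean and camera direction did not all share a sign for S phase, pachytene, piRNA, p53, m6A and RNA decay genes here, for integrated stress and RNA decay genes in clusters 1 and 2, and for m6A genes in all germ cells. Too few genes of undifferentiated spermatogonia were measured here to test that list. The Sertoli list could not be tested in any class for the same reason. Its genes summed to 74.3 CPM in cluster 1 of WT and 44.0 and 119 in KO A and KO B, to 22.1 in cluster 3, and to 34.6 and 29.7 in cluster 4 of the KO libraries. Over 9299 genes limma called 3480 higher and 2703 lower, and DESeq2 1674 and 1806. The limma p values here rest on a pooled spread with infinite prior degrees of freedom, so they are smaller than 3 libraries can carry by themselves.

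**Figure D2:**
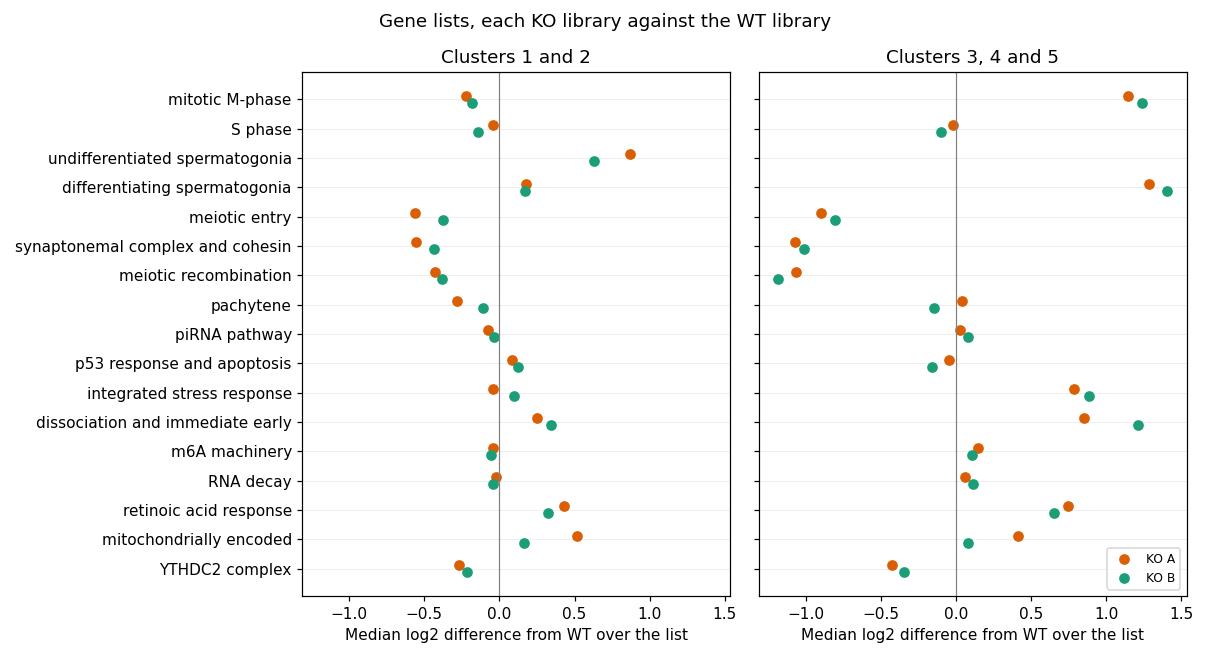
Median log2 difference from WT over the measured genes of each list (horizontal axis), with 1 point per KO library and list, in clusters 1 and 2 (left) and clusters 3, 4 and 5 (right, where the undifferentiated list has too few measured genes). For M-phase genes the points lie at -0.22 (KO A) and -0.18 (KO B) on the left and at 1.15 and 1.24 on the right.

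Whether mitotic and meiotic transcripts stood in the same cells was then counted per cell, after thinning to 5000 UMIs. In cells with at least 3 UMIs of the synaptonemal complex and cohesin list, an M-phase UMI was seen in 100% of 1139 WT, 1514 KO A and 1839 KO B cells (exact lower bounds 99.7%, 99.8% and 99.8%), so this measure was saturated. In clusters 3, 4 and 5 the median cell held 22 M-phase UMIs in WT and 35 and 40 in KO A and KO B, and 50 synaptonemal complex UMIs in WT and 26 and 29. A Plk1 UMI was seen there in 13.3% of WT cells, 55.8% of KO A cells and 58.4% of KO B cells (21.5%, 66.8% and 73.0% before thinning). Cdk1 was seen in 17.7% of WT cells, 65.3% of KO A cells and 65.0% of KO B cells (33.0%, 83.1% and 83.3% before thinning). Ccna2, the cyclin A2 gene, was seen in 30.1% of WT cells, 77.1% of KO A cells and 77.6% of KO B cells (51.8%, 91.7% and 94.0% before thinning). These 3 have wide gaps among the 20 genes, and Bub1 went the other way (93.4%, 84.3% and 82.8%), as did Tpx2 (79.6%, 74.0% and 77.9%), while Top2a and Cenpf were seen in 96.5% or more of the cells of each library. No cell type that should lack these transcripts was captured in numbers. With 20 or more M-phase UMIs asked of a cell, the shares in these clusters were 68.1% of WT, 86.2% of KO A and 86.2% of KO B. With 30 or more, both numbers chosen after seeing the data, the shares in these clusters were 25.2% of WT (exact interval 21.3 to 29.5), 58.7% of KO A (55.4 to 61.9) and 66.1% of KO B (63.0 to 69.1). Among all cells with 40 to 59 synaptonemal complex UMIs, the median M-phase count was 21 in 234 WT cells, 47 in 89 KO A cells and 48 in 127 KO B cells. Among those with 20 to 29 it was 47.5, 35.5 and 43.

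**Figure D3:**
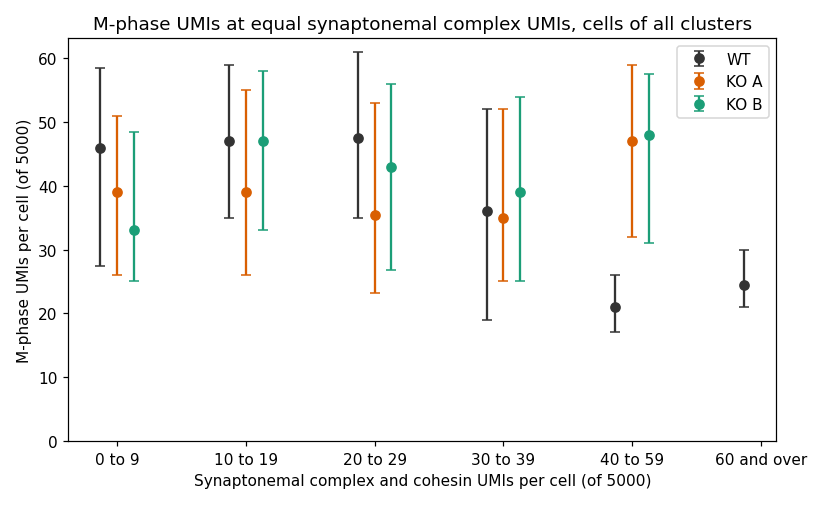
Median M-phase UMIs per cell thinned to 5000 UMIs (vertical axis) against bins of synaptonemal complex and cohesin UMIs of the same cells (horizontal axis), 1 point per library and bin; error bars are quartiles over cells, and bins with under 20 cells of a library are not drawn. The quartile ranges overlap up to 39 UMIs, and at 40 to 59 the medians are 21 in WT and 47 and 48 in the KO libraries.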

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

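Of the tests in this part, those of doublets, of free RNA at one share and of equal synaptonemal complex UMIs were chosen after the result was seen, and the test of spermatogonial free RNA before. The genes with opposite signs were named after their values were seen.

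The mitotic M-phase list had a median log2 difference of -0.20 in clusters 1 and 2 (though the median cell of cluster 2, thinned, held 48 such UMIs in WT, 44 in KO A and 48 in KO B) and of 1.19 in clusters 3, 4 and 5, where 16 rose and 1 fell (camera adjusted p = 4.8e-04 and 7.4e-14, and 0.488 and 0.540 with an estimated correlation), with both KO libraries on one side in each; the difference between the classes was not tested. Doublets of a spermatogonium and a spermatocyte are argued against for cluster 4 only. With called doublets removed, the median in KO cluster 4 against WT cluster 3 was 1.23 (1.15 and 1.31). Cells of cluster 4 also held fewer UMIs than those of cluster 2 (medians of 8149 and 9669 in KO A, 8563 and 11798 in KO B). For cluster 5, which that test left out, doublets stay open. Its KO cells held medians of 16099 and 16156 UMIs, above cluster 2, and 1 and 14 of them were called doublets. Free RNA at one share in every droplet, with the composition of its library, could give at most 32.0% of the KO excess in KO A and 27.1% in KO B (mean 29.5%). That composition was not measured, so free RNA of another make-up stays open. The first such test, in which 1 of 7 spermatogonial genes in KO A and 0 of 7 in KO B (mean 7.14%) were low in the KO meiotic clusters, decided nothing by itself. An earlier stage of the KO cells may account for the 405 KO A and 405 KO B cells of these clusters with 20 to 29 synaptonemal complex UMIs, where the KO to WT ratio of M-phase medians over all clusters was 0.826 (0.747 and 0.905) and the 24 WT cells of cluster 4 held more M-phase UMIs than its KO cells (medians 43.5 against 34 and 39). It is left open for the 259 and 305 cells with 30 to 39, where the ratio was 1.03 (0.972 and 1.08) over all cells but 1.39 and 1.59 in cells of 10000 UMIs or more. For the 89 and 127 KO cells with 40 to 59 the ratio was 2.26 (2.24 and 2.29, and 2.33 and 2.11 in the deeper cells). Matching there was not exact: the deeper cells had medians of 48.9 synaptonemal complex UMIs per 5000 in WT and 43.6 and 42.8 in KO. The matching list was itself lower in KO, so an earlier stage is not excluded for these cells either. An effect of the genotype on their mitotic transcripts is a hypothesis that 1 WT library leaves untested. Among all cells with 20 to 29, 8.82% of WT, 82.7% of KO A and 73.4% of KO B cells were in clusters 3, 4 and 5.

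Of 389 genes called in both clusters 1 and 2 and clusters 3, 4 and 5, 11 had opposite signs with both KO libraries on one side in each, and the difference was not tested. The 7 that were higher in the first and lower in the second included the kinesin light chain gene Klc3 (0.83 and -2.03), the BMP receptor gene Bmpr2 (0.55 and -0.61) and Kmt2c (0.63 and -0.36), and the 4 that went the other way were B2m (-0.70 and 0.56), Wdr77 (-0.51 and 0.53), Cops3 and Ormdl1.

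A deposited column that no comparison used, the log2 sum over genes with a U-rich motif, had a median of 6.27 and 6.28 in cluster 5 of KO A and KO B, above the 5.99 of WT cluster 3. In KO cluster 4 it was below, at 5.86 and 5.90. Depth had the same order, with 8149 and 8563 median UMIs in cluster 4 and 16099 and 16156 UMIs against 12210, and the sum was not compared at equal depth.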

How the results depend on the processing

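The alternatives added after seeing the data were TMM scaling in limma, robust moderation, other pseudocounts, deeper cells, equal cells and removal of the 34 cells. Single clusters, DESeq2 without its filter on low means, and 20 and 30 M-phase UMIs were added then too. edgeR with TMM and Leiden resolution 1 had been named in advance, and limma and the authors' clusters took their place in the main result. No paired analysis was possible because WT has 1 library, so the groups share fewer than 2 replicate numbers. Leaving out a KO library left 1 against 1 and no test, so only values are given: Ythdc2 in the KO libraries was 42.6 to 47.0 CPM, and the share of clusters 3, 4 and 5 was 51.3 to 60.9%. Filters of 1000 and 2000 UMIs removed 0 cells and so test nothing, and resolution 2 does not apply to all germ cells together.

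Counts of calls moved by over 1.5 times in these cases, and the cause was not tested. In all germ cells DESeq2 called 1196, and 1112 without its filter, against 3188. In clusters 3, 4 and 5 it called 3480 and 3304 against 6183. Clusters 1 and 2 moved most, from 490 to 178 with DESeq2 and 73 without its filter, 1259 with edgeR and TMM, 2015 with edgeR and RLE, 905 without doublets, 818 without the 34 cells, 1218 in cells of 10000 UMIs or more, 1077 with equal cells, 318 in cluster 1 alone and 1106 with clusters at resolution 1. Their shares of higher calls were 9.55% with DESeq2 and 40.1% with edgeR and RLE.

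List calls by camera ended with an estimated correlation, at adjusted p = 0.666 in all germ cells, 0.488 (S phase and mitochondrially encoded genes 0.672) in clusters 1 and 2 and 0.540 in clusters 3, 4 and 5. With 1 residual degree of freedom that version could hardly pass any list, so the loss decides nothing. With RLE scaling the YTHDC2 complex had 5.7e-04, 0.0678 and 0.145 in these classes, differentiating spermatogonia 0.0580 in clusters 1 and 2, and immediate early genes 0.0649 in clusters 3, 4 and 5. Co-detection over all clusters was 97.6%, 99.5% and 99.8% with the differentiating list and 61.3%, 64.7% and 73.7% at 30 M-phase UMIs, and 85.6%, 89.5% and 90.7% at 20, in WT, KO A and KO B. At 50 CPM the pair counts were 48, 37 and 1, since fewer genes qualify. The share of clusters 3, 4 and 5, higher in KO, turned to higher in WT at resolution 2, with 61.1%, 57.4% and 43.0%. It stayed higher in KO at resolution 1, with 462 of 1151 WT, 931 of 1522 KO A and 958 of 1855 KO B cells. Of the values of the 23 genes of each class taken in advance or by rank, and of list medians without a KO library, 15 gained a call, 30 lost it (most of them with DESeq2, where a value without an adjusted p counts as not called), 0 that had passed a test changed sign outside the fits of cluster 1 alone, and 2 (both of Rbm46) and 7 (of S phase, immediate early, RNA decay, integrated stress and pachytene genes) that had not passed one did. With RLE the medians of 5 lists that had not passed camera changed sign (M-phase and m6A in all germ cells, RNA decay in clusters 1 and 2, pachytene and piRNA in clusters 3, 4 and 5). Of the named genes that are list members, calls were gained and lost over all alternatives 16 and 57 times in all germ cells, 108 and 46 in clusters 1 and 2 and 0 and 18 in clusters 3, 4 and 5, and 2 called values changed sign, Egr1 in all germ cells (0.29 in deeper cells) and Dmc1 in clusters 1 and 2 (0.00 at resolution 2). In cluster 1 alone 14 of 39 named genes called in clusters 1 and 2 had the opposite sign, and 9 without the 34 cells, among them Ccnb3 (1.19), Cox7b (-0.18), Cox8a (-0.12) and Camk2n1 (-0.03), none with a call there by limma. In clusters 4 and 5, each against WT cluster 3, this held for 0 of 72. Genes under 0.05 normalised UMIs per cell were not tested at this depth, and in clusters 1 and 2 limma found 31% of the simulated changes of log2 0.5. Xrn1 lost its call in clusters 3, 4 and 5 with DESeq2 and at resolution 2, and Meioc gained one in clusters 1 and 2 in 10 settings.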

Other observations

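Of the tests in this part, those of a variant acting in every cell, of a mix with WT cells and of evenly spread free RNA were chosen after the result was seen, and those of positions near Ythdc2 and of strain blocks before; the gene families of the next paragraph were also chosen after.

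Genes of the cytosolic ribosome were lower in KO cells of clusters 3, 4 and 5, where 69 of 83 ribosomal protein genes fell and 2 rose, Rps4x (1.11) and Rps3a1 (0.48), with a median log2 of -0.74 and Rps12 at -1.58. Other scalings and tests called 47 to 66 of them lower, while in clusters 1 and 2, where 77 of 83 lay below 0 (median -0.23), limma called 0 (2 at an unadjusted p under 0.05), edgeR 0 and DESeq2 3. Tubulin genes went the other way, with 9 of 14 higher (6 to 8 under other scalings and tests), led by Tuba1b (3.82) and Tubb5 (2.93), and 1 lower, Tuba4a (-0.68). Of 6 H2 genes of the major histocompatibility complex 5 fell and 1 rose, H2-T23 (2.07), with a median of -1.59. DESeq2 called 4 of them lower and did not call Tuba4a. H2-D1, lower in KO in clusters 1 and 2, was also lower within cluster 4, at 119 CPM in WT and 37.0 and 72.6 in KO A and KO B. The tests of variants below cover no H2 gene, so a strain difference on this hybrid background stays open for them. The rise of Cox7b and Cox8a was not shared by the respiratory chain as a whole, whose nuclear genes counted 18 higher, 30 lower and 47 not past the test of 95 (9 to 14 higher and 18 to 33 lower in the alternatives). In WT clusters 1, 2 and 3, Cox7b stood at 128, 52.2 and 9.57 CPM and Cox8a at 905, 159 and 51.2 CPM, and in KO cells Cox7b stood between 126 and 246 CPM and Cox8a between 562 and 956 CPM in every cluster. Prdx3 was at 9.07 and 2.02 CPM in WT clusters 2 and 3 and at 23.4 to 51.0 in KO clusters 2, 4 and 5, and Camk2n1 at 19.5 and 1.29 against 29.3 to 52.7.

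Of 6091 genes that could qualify, 8 were shifted by a log2 of 1 or more in the same direction in both classes of clusters and both KO libraries, 6 higher (Cox7b, Cox8a, Camk2n1, Mtap, Prdx3 and the predicted gene Gm8797) and 2 lower (Ccnb3 and Tex12). Variants carried along beside the Ythdc2 mutation are argued against for these 8, as 0 of them lay within 20 Mb of Ythdc2. Of the 6091 genes, 78 lie in that window. For Reep5, Dcp2, Egr1 and Kif20a, which are inside it and not among the 8, such variants stay open. A variant acting in every cell is argued against for 7 of them as a set by cluster 1, taken without its cells with smooth muscle, stromal or globin UMIs. There the median share kept of the change seen in clusters 1 and 2 was -0.0218 (quartiles -0.0902 to 0.139). Single genes are not decided by it. The WT library held 35 such cells, Prdx3 kept a log2 of 0.41 there, and Ccnb3 was low, at 5.23 CPM in WT cluster 1. It stays open for Gm8797, which kept 1.11 of that change. Strain blocks elsewhere in the genome cannot be told apart from the genotype, because 0 pairs of the 8 lay within 2 Mb of each other and random sets also had a median of 0, so a count of 0 excludes nothing. For Cox7b, Cox8a, Prdx3 and Camk2n1, whose WT levels stood lower in cluster 3 than in cluster 2, a loss of that course in KO remains a hypothesis with no test of its own.

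Ythdc2 UMIs remained in KO cells at 0.5 to 0.609 per cell in every cluster. WT cells mixed into the KO libraries are argued against, since 2.11 times as many KO cells held a UMI as such a mix would give (1.95 and 2.26). Free RNA spread evenly over droplets stays open. Abundant genes of the meiotic clusters fell in cluster 1 to a median of 0.186 of their library level, where Ythdc2 kept 0.545 and 0.537. That bears only on free RNA with the composition of its library, which was not measured. The count per KO cell changed little, as an even spread would give, while median depth ran from 8149 (KO A) to 18240.5 UMIs (KO B). In WT it was 0.8 in cluster 1 and 2.52 in the authors' differentiating spermatogonia. Transcripts of the KO allele itself also stay open and were not tested, as reads along the gene were not used here.

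The U-motif score of a gene had a Spearman rho of -0.06 with its log2 change in clusters 3, 4 and 5 and -0.13 in clusters 1 and 2, across genes, which are not independent replicates, and of 0.21 with mean CPM. In KO A, 1 cell of cluster 2 held 2748 globin UMIs, 21.8% of its total. Stra8 was at 1658 CPM in WT cluster 3 and at 2185 and 1997 CPM in KO cluster 5 but 1175 and 1089 CPM in KO cluster 4, and Wdfy1 was at 23.9 CPM in WT cluster 3 and 8.56 to 12.2 CPM in KO clusters 4 and 5.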
